A study of Mus musculus with 2 samples.

How the data were processed

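Droplet single-cell RNA libraries (10x Genomics 3' chemistry) were made from the optic cup of Abca4 knockout mice, 1 library from eyes given a GFP control vector and 1 from eyes given a miR-181a/b sponge vector. A sponge is a transcript with many binding sites for a microRNA, meant to keep it from its targets. Each group holds 1 library, and the number of mice behind each is not given in the sources used here. The series places the injection at 2 months of age and the collection 4 months later, whereas the sample labels give an age of 4 months. This disagreement was left open. Per the series both eyes of each mouse were injected, but each library is 1 sample whose cells are not assigned to mice in the sources used here, so no paired comparison was made.

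The deposited matrices hold counts of unique molecular identifiers (UMIs) per gene and cell barcode, without normalization. Per the submitters' processing notes they were made with Cell Ranger 7.0.0 on mm10. How intronic reads were handled and how barcodes were called as cells is not given in the sources used here. Both matrices list the same 32286 features, the last of which is the eGFP sequence added to the mouse genes. The library labelled GFP held 39461 barcodes with 123040365 UMIs, and the library labelled sponge held 23267 barcodes with 132067896 UMIs.

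Barcodes with at least 300 genes, at least 500 UMIs and at most 25% mitochondrial UMIs were kept. This removed 176 barcodes from the library labelled GFP and 67 from the library labelled sponge. Doublets were scored per library with Scrublet as built into scanpy 1.11.5. Its automatic thresholds of 0.55 and 0.65 marked 0 cells in either library, so the caller did not work on these libraries and no doublets were removed. A comparison that keeps the called doublets, fixed before the data were examined, was therefore identical to the main setting and was not run. An alternative without the 10% of cells with the highest scores in each library was added after seeing the data.

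Cells of both libraries were clustered together on log-normalised counts (10000 UMIs per cell), 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1 (leidenalg 0.10.2, igraph 0.11.9), without batch correction. This gave 26 clusters, and resolution 2, an alternative, gave 44. Clusters were named from marker lists fixed before the data were examined, as resembling a class. The rule itself was set after seeing the clusters: at least 3 markers at least 2-fold over the median cluster, no other class at 0.5 or more of the best score, and no other class leading among the 10 genes most enriched in the cluster. Related classes, such as Müller glia and astrocytes, did not count against each other. Clusters that failed it stayed unnamed. They held 24.7% of cells in the library labelled GFP and 30.2% in the library labelled sponge. Of the 2 clusters resembling Müller glia, 1 led with an astrocyte marker and none of its own, so the clusters, numbered 13 and 14, were compared separately.

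UMI counts were summed per class and library and scaled to a common class total as CPM. A gene was measured in a class with at least 20 counts over both libraries. The log2 ratio is the library labelled sponge over the library labelled GFP, with 0.5 added to both counts. With 1 library per group there is no replicate error, so no test was run, no p-value is given and no number of changed genes is counted. Intervals are 95% intervals for counting error alone: exact Poisson for CPM, exact Clopper-Pearson for shares of cells, and the exact binomial interval of the 2 counts for ratios. They do not cover differences between mice, eyes, injections or dissociations. Where a library held 0 counts, the ratio is a bound against 3 counts in that library, and the limit of a share of 0 is 3 cells.

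The 24 gene lists and the rule for named genes were fixed before the data were examined. A list is described by the median log2 ratio of its measured members, the members above and below 0, and the percentile of that median among 10000 random lists of the same size matched on mean CPM in 20 bins. Intervals of a median come from 1000 Poisson draws of the counts. Named genes are the 12 highest and 12 lowest in rods, Müller glia and retinal pigment epithelium (RPE), and the 6 highest and 6 lowest elsewhere. They were ranked by the interval bound nearest 0 among genes with at least 50 counts, at least 20 CPM in a library, and a class mean of at least 0.1 of that in the highest class. Members of a list were also named, and some genes are not reported here. A class needed 50 cells in each library. Clec7a, a member of the list for disease-associated microglia, was not analysed here.

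Annotated 3' UTRs (GENCODE M21) were found for 20691 genes, of which 3441 hold a miR-181a/b seed match (TGAATGT, a 7mer-m8 or 8mer site). The seed shift is the median log2 ratio of measured genes with a match minus that of genes with none. It was set against 10000 random lists matched on mean CPM and UTR length, and against the 210 7-mers of the same base composition. Gene coordinates are those of mm10.

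The procedure was tested on simulated data built on the counts of rods and RPE, with 200 genes changed by 1.5 or 2 times. The intervals held the true ratio for 95.5% to 95.6% of genes, and 98.5% to 100% of changed genes had the right sign. A raised list reached percentile 100 in each of the 4 settings, and 5 to 7 of 100 unchanged lists fell outside the central 95%. This covers counting error alone.

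The settings varied were a stricter filter on cells (at least 500 genes, 1000 UMIs and at most 10% mitochondrial UMIs), resolution 2, classes by highest marker score, the neural retina as denominator, median-of-ratios scaling, totals without mitochondrial, ribosomal and rod genes, cells thinned to 1000 UMIs, cells weighted equally, subtraction of the rod profile, other count filters and added constants, and other definitions of a seed site and its background. Alternatives chosen after seeing the data left out cells with high Scrublet scores, left out the unnamed clusters, counted cluster 7 with rods, weighted cells equally for the lists, and took each of 2 RPE clusters of resolution 2 alone. Software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.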

Results

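Single-cell RNA libraries were compared from the optic cup of mice that lack Abca4, the photoreceptor transporter that clears retinoid by-products and whose loss is a model of Stargardt disease. Per the series, 1 eye of each mouse received a subretinal AAV vector carrying a sponge for miR-181a and miR-181b, and the other eye a control vector labelled GFP. The comparison addresses how inhibition of these microRNAs alters the cells of a degenerating retina. Each group held 1 library, so the values below describe 2 libraries and carry counting error alone. The library labelled GFP gave 39285 kept cells with a median of 2415 UMIs, and the library labelled sponge gave 23200 kept cells with a median of 2980.5 UMIs. Their total counts were 123040365 and 132067896 UMIs. Mitochondrial transcripts took a median of 11.2% of UMIs per cell in the library labelled GFP and 8.87% in the library labelled sponge. Depth differed more within classes. Of the 9 classes and clusters compared, the ratio of median UMIs, sponge over GFP, ran from 0.485 in RPE to 3.11 in Müller cluster 14.

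The eGFP feature was counted almost only in the library labelled sponge. The eGFP sequence had 12 UMIs in the kept cells of the library labelled GFP and 5484 UMIs in those of the library labelled sponge. In cells resembling retinal pigment epithelium (RPE), the pigmented layer that a subretinal injection reaches, eGFP stood at 1.25 CPM (95% interval 0.573 to 2.38) in the library labelled GFP and 681 CPM (662 to 700.6) in the library labelled sponge. It was seen in 7 of 966 RPE cells (0.725%, exact interval 0.292 to 1.49) of the library labelled GFP and in 144 of 504 (28.6%, 24.7 to 32.7) of the library labelled sponge, at median depths of 6406 and 3106.5 UMIs. With each cell thinned to 1000 UMIs, these shares were 0.315% and 14.7%, against 0 of 5272 rods, which allows a share of up to 0.0569%, and 0.889% of rods. The groups are therefore named by their labels, the library labelled GFP and the library labelled sponge, and each direction below rests on labels that the eGFP counts do not bear out. Whether the sponge vector also encodes eGFP is not given in the sources used here.

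**Figure D1:**
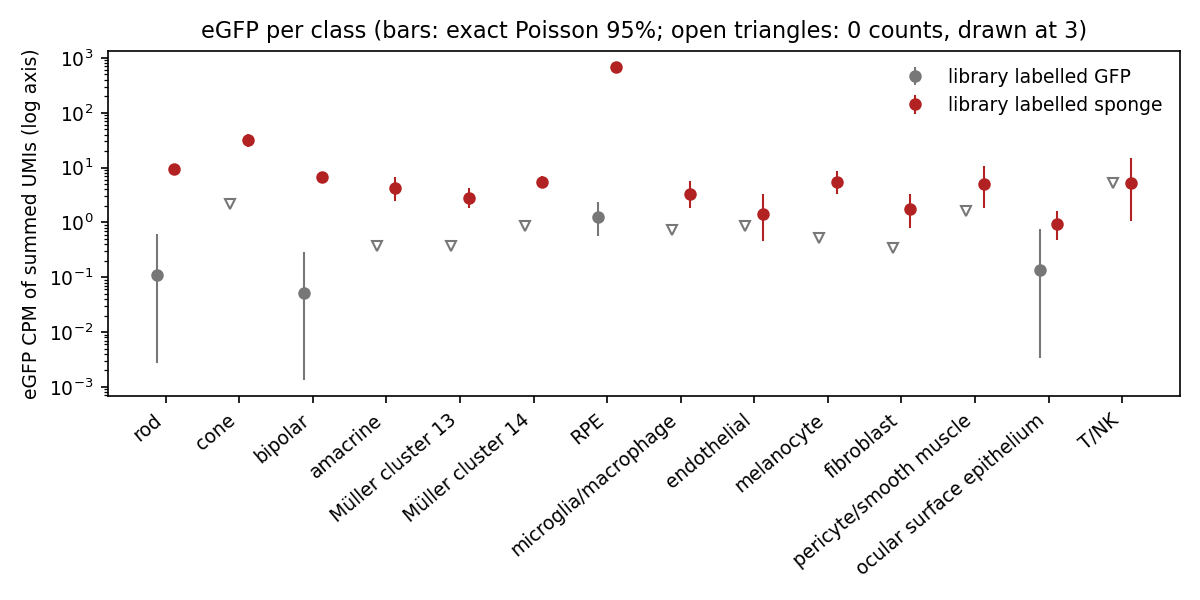
eGFP CPM of summed UMIs (log axis) in each class and library, with exact Poisson 95% intervals; open triangles mark classes with 0 counts, drawn at 3 counts. In the library labelled sponge the RPE class stands at 681 CPM and rods at 9.34 CPM.

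Both libraries are labelled as Abca4 knockout, and Abca4 transcripts (ENSMUSG00000028125, mm10 chromosome 3, 122044443 to 122180123) were counted in both. Rods had 126 CPM (119 to 134) in the library labelled GFP and 134 CPM (128 to 140) in the library labelled sponge, and RPE had 102 CPM (95.1 to 110.1) and 117 CPM (109.5 to 126). A 3' tag outside the deleted part of a gene is still counted, so these values do not check the genotype.

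The cell classes differed in their shares. Rods were 13.9% of kept cells (13.6 to 14.3) in the library labelled GFP and 25.3% (24.8 to 25.9) in the library labelled sponge. Amacrine cells, inhibitory interneurons of the retina, were 4.91% (4.69 to 5.12) and 2.30% (2.11 to 2.498). Bipolar cells, which relay photoreceptor signals, were 19.5% (19.1 to 19.9) and 15.6% (15.1 to 16.1), and endothelial cells were 2.78% (2.62 to 2.94) and 1.69% (1.53 to 1.86). Cones stood at 1.82% (1.69 to 1.96) and 1.84% (1.68 to 2.03), and the microglia and macrophage class at 3.04% (2.87 to 3.22) and 3.12% (2.90 to 3.35), with overlapping intervals. RPE made up 2.46% (2.31 to 2.62) and 2.17% (1.99 to 2.37).

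Cells from around the retina also had lower shares in the library labelled sponge, with fibroblasts at 7.88% and 2.73%, melanocytes at 4.12% and 1.57%, pericytes and smooth muscle at 1.70% and 0.987%, and ocular surface epithelium at 2.70% and 1.802%. T and NK cells were 0.507% and 0.405%. Rods lay in different clusters, 85.0% of those labelled GFP in cluster 6 and 72.7% of those labelled sponge in cluster 8. An unnamed cluster led by haemoglobin and rod genes, cluster 7, held 7.75% and 22.3% of cells. Under the stricter filter on cells the log2 ratio of the rod share was 3.30 in place of 0.87 and that of the bipolar share was 0.44 in place of -0.32. It was 1.35 for cones and -0.92 for RPE, and with each cell assigned by its highest marker score it was -0.52 for cones, -0.26 for amacrine cells, 0.42 for microglia and macrophages, 0.82 for ocular surface epithelium and 0.0318 for pericytes and smooth muscle, so these shares depend on how cells were kept and named.

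**Figure D2:**
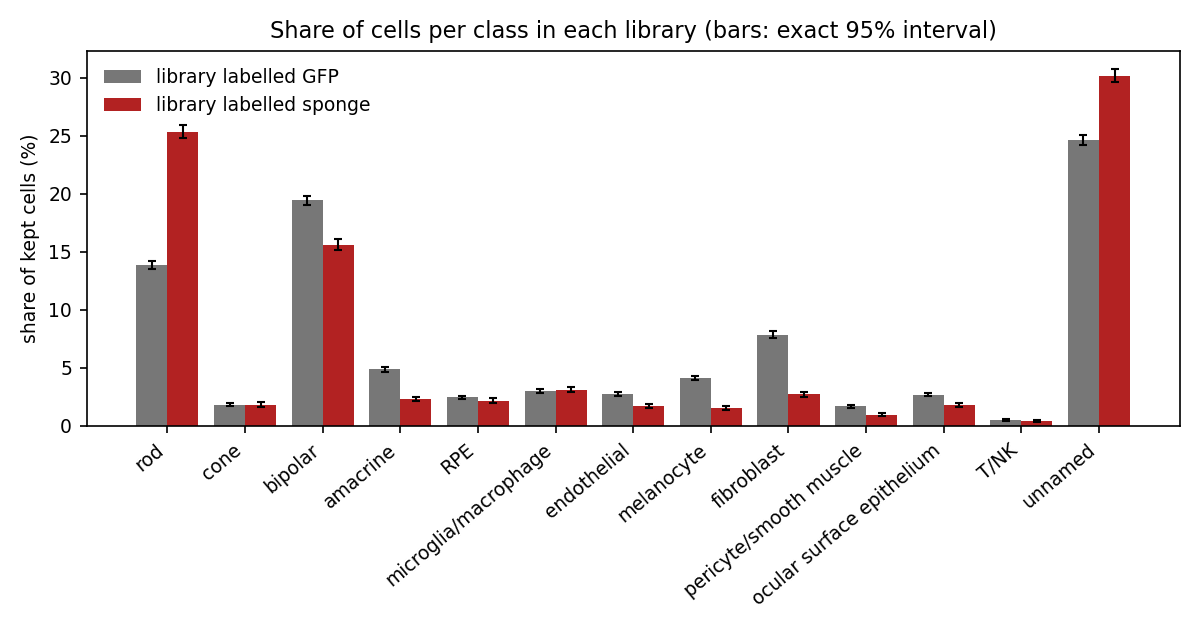
Share of kept cells (%) per class in each library, with exact Clopper-Pearson 95% intervals. Rods stand at 13.9% and 25.3%, and amacrine cells at 4.91% and 2.30%.

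Of the 9 classes and clusters compared, RPE had the highest medians of the antigen presentation and interferon lists. Genes of antigen presentation, which load and display peptides on MHC molecules, were higher in RPE of the library labelled sponge for 15 of 15 members, with a median log2 ratio of 2.97 (2.86 to 3.19) at percentile 100 of random lists. Genes of the interferon response were higher for 19 of 20 members, with a median of 2.00 (1.71 to 2.13) at percentile 100, and Ifi27l2a was the exception at 16.3 and 5.75 CPM. Of the 12 genes ranked highest in RPE, Gbp4, Gbp6, Gbp8, Gbp10, Igtp and Iigp1 encode interferon-induced GTPases. Gbp4 (chromosome 5, 105115767 to 105139586) stood at 7.52 CPM (5.65 to 9.81) in the library labelled GFP and 292 CPM (279.7 to 305) in the library labelled sponge, a log2 ratio of 5.27 (4.89 to 5.70).

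Other genes of that set act in antigen processing or signalling. Psmb9 (chromosome 17, 34181987 to 34187764), a subunit of the immunoproteasome, stood at 9.47 CPM (7.35 to 12.0) and 203 CPM (192 to 213). Cd74 (chromosome 18, 60803848 to 60812652), the invariant chain of MHC class II, stood at 65.2 CPM (59.4 to 71.4) and 972 CPM (949 to 995), and H2-DMb1, which also serves class II loading, at 1.67 and 41.5 CPM. H2-K1 (chromosome 17, 33996017 to 34000347), an MHC class I heavy chain of the antigen presentation list but not of that set, stood at 88.2 and 655 CPM. Cxcl10, a chemokine that attracts T cells, stood at 14.6 CPM (12.0 to 17.7) and 226 CPM (215 to 238). Ubd stood at 8.22 and 167 CPM and Ly6a at 50.6 and 1084 CPM.

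The RPE class was not uniform. At resolution 2, 789 of its 966 cells labelled GFP and 175 of its 504 labelled sponge lay in cluster 34, and 150 and 268 in cluster 43. With cells from outside the class these clusters held 809 and 183 cells, and 190 and 312. The genes that set cluster 43 apart include eGFP, Ly6a, Ubd, Iigp1 and Gbp4. The split was drawn partly by these genes, so it does not show which RPE cells carry the difference. In cluster 34 alone, an alternative added after seeing the data, the interferon list had a median of -0.38 and the antigen presentation list 0.57, with Cd74 at 21.5 CPM (18.1 to 25.2) and 66.6 CPM (59.4 to 74.5). In cluster 43 alone they were 1.82 and 1.83, with Gbp4 at 94.5 CPM (68.4 to 127) in the library labelled GFP and 782 CPM (748 to 817) in the library labelled sponge. The eGFP sequence was not confined to cluster 43. In the library labelled sponge it stood at 269 CPM (254 to 284) in cluster 34 and 1406 CPM (1360 to 1453) in cluster 43.

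Functional RPE genes gave a mixed picture. The RPE function list had 10 members above and 10 below 0, with a median of -0.02 at percentile 65.0. Under total scaling the median of all RPE genes was -0.20, against 0.04 with median-of-ratios scaling, and with the latter scaling the list's median was 0.22. The visual cycle list had 11 of 15 members above 0 in RPE and a median of 0.24 at percentile 94.5. Its highest member, Rdh5, which makes 11-cis retinal, stood at 2078 and 4202 CPM, although Rdh5, Rpe65, Ttr, Rgr and Lrat also define the cluster. Oxidative stress genes had a median of 0.40 (14 of 22 members above 0, percentile 99.96), among them Prdx6 at 244 and 486 CPM and Gpx4 at 3299.8 and 5338 CPM. Lysosome and autophagy genes had a median of 0.32 (21 of 26, percentile 99.8) and genes of the unfolded protein response 0.39 (12 of 14, percentile 99.5).

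Glycolysis (0.20, percentile 93.1), apoptosis (0.04, percentile 89.7), complement (0.14, percentile 94.1) and cholesterol synthesis and export (-0.31, percentile 13.2) lay within the range of random lists in RPE. The cytokine and inflammasome list had a median of -1.46 at percentile 0 with 5 members above and 8 below 0, and it turned to 0.43 in cells thinned to 1000 UMIs. Of the genes ranked lowest in RPE, Il1rapl2, Cntn5, Hs3st4 and Zfp804b also lead an unnamed cluster of bipolar character, which held 9.36% of cells in the library labelled GFP and 1.26% in the library labelled sponge. The others were Lalba at 262 and 43.5 CPM, Kcnip4, Unc13c, Kirrel3, Ulk4, Lrrc2, Wdr95 and Adcy2.

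**Figure D3:**
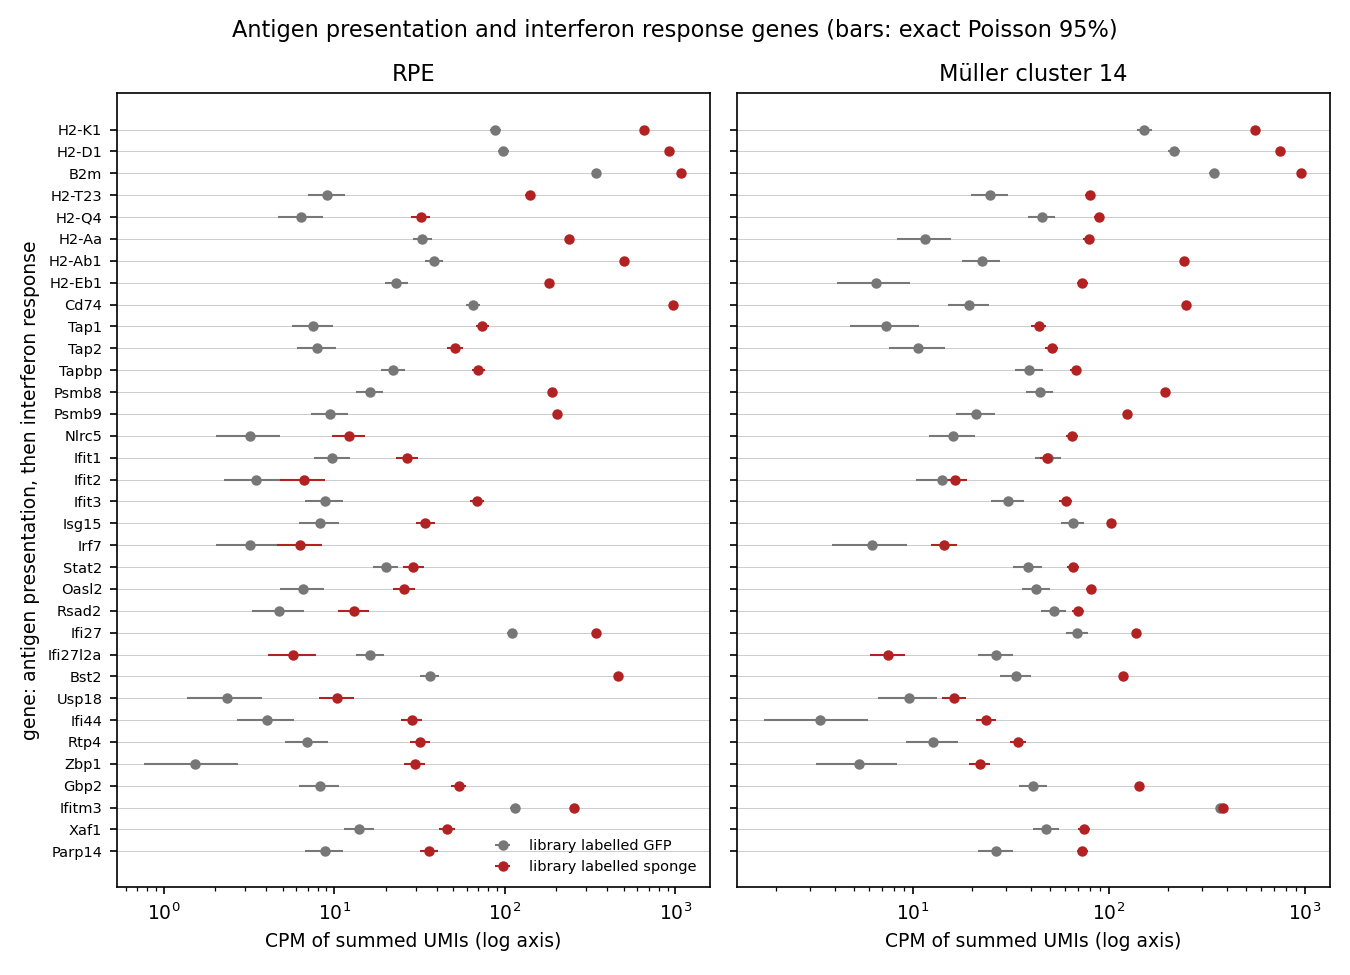
CPM of summed UMIs (log axis) of members of the antigen presentation and interferon response lists in RPE and in Müller cluster 14, in each library with exact Poisson 95% intervals. In both panels all 15 antigen presentation genes are higher in the library labelled sponge, with Cd74 in RPE at 65.2 and 972 CPM.

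Müller glia, the radial support cells of the retina, were compared in 2 clusters. In cluster 14, which is led by stress and reactivity genes such as Fos, Gfap and Lcn2, antigen presentation genes were higher in the library labelled sponge for 15 of 15 members (median 2.12, 1.91 to 2.35, percentile 100) and interferon response genes for 18 of 20 (median 0.95, 0.79 to 1.08, percentile 100). Among the 12 genes ranked highest there, Ly6a stood at 19.2 CPM (14.9 to 24.3) and 442 CPM (431 to 454), Igtp at 12.7 and 177 CPM, Iigp1 at 22.8 and 262 CPM, and Gbp4 at 12.1 and 115 CPM. The others were Tgtp2, Irgm1, Irgm2, Ifi47, Gbp8, Gbp10, Psmb9 and Tnfsf10. At resolution 2, 16 of the 977 cells labelled GFP and 299 of the 1223 labelled sponge of cluster 14 lay in a cluster led by Igtp, Ly6a and Gbp genes, which was drawn partly by the genes compared. In cluster 13 the medians were 0.67 for antigen presentation (11 of 15, percentile 100) and 0.30 for the interferon response (13 of 19, percentile 95.8).

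The glial reactivity list went the other way within each cluster. Its median was -0.61 in cluster 13 (4 of 20 members above 0, percentile 0) and -0.29 in cluster 14 (9 of 21, percentile 0.08). Cluster 14 itself held 2.49% of kept cells in the library labelled GFP and 5.27% in the library labelled sponge, and cluster 13 held 7.58% and 4.96%. The medians within clusters therefore do not give the reactivity of Müller glia as a whole. In cluster 14, Serpina3n, an acute-phase gene of reactive glia, stood at 509 CPM (486 to 533) and 87.7 CPM (82.6 to 93.1), Timp1 at 203 and 18.4 CPM, Steap4 at 278 and 27.9 CPM, the complement gene C3 at 73.0 and 6.19 CPM, and the metallothionein Mt1 at 4064 and 1270.0 CPM. Gfap, the intermediate filament that marks gliosis, stood at 112 and 155 CPM, and Vim and Socs3 were also above 0 in that cluster. Hexokinase 2 (Hk2) stood at 139 and 38.5 CPM in cluster 14 and at 153 and 40.2 CPM in cluster 13. The other genes ranked lowest in cluster 14 were Megf11, Tnfaip2, Gng13, Kcnb2 and Neurod4.

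Lcn2 (chromosome 2, 32384633 to 32388252), a secreted acute-phase protein, had 442 CPM (438 to 446) over all kept cells of the library labelled GFP and 31.5 CPM (30.5 to 32.5) over those of the library labelled sponge. It leads Müller cluster 14, where it stood at 5115 and 129 CPM, so its difference there is tied to how the cluster was drawn. It was lower in the library labelled sponge in the other classes as well, with 336 and 5.77 CPM in amacrine cells, 189 and 9.34 CPM in rods, and 170.5 and 68.1 CPM in RPE. In the other named classes, its level in the library labelled GFP ran from 146 CPM in cones to 349 CPM in melanocytes. This range leaves out the unnamed clusters, and Lcn2 is among the leading genes of unnamed cluster 20. Free RNA from cluster 14 was not told apart from expression in these classes.

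Homeostatic Müller genes were higher in both clusters of the library labelled sponge, although Glul, Slc1a3, Rlbp1, Aqp4 and other members are also the markers that named these clusters. The list had a median of 0.54 in cluster 13 (14 of 16, percentile 99.7) and 0.42 in cluster 14 (13 of 16, percentile 99.7). Median UMIs per cell were 2456 and 7310 in cluster 13 and 3251 and 10126 in cluster 14. Mitochondrial UMIs were 9.45% and 3.92% of the total in cluster 13 and 8.22% and 4.44% in cluster 14. Expression of these genes was not told apart from these differences in depth and cell quality. The cells behind cluster 13 differed between libraries, since at resolution 2 its 2978 cells labelled GFP lay mostly in cluster 18 (2386, and 143 labelled sponge) and its 1151 labelled sponge in cluster 19 (938, and 262 labelled GFP). In cluster 13, glutamine synthetase (Glul) stood at 2857 and 4965 CPM, Rlbp1, which binds visual cycle retinoids, at 1019.99 and 1759.8 CPM, and the lipid carrier Apoe at 3376 and 6700.0 CPM. Of the genes ranked highest in cluster 13, Prss56 stood at 32.7 and 84.4 CPM and Cd9 at 389.8 and 812 CPM. Visual cycle genes as a list were lower, with medians of -0.77 and -0.74 at percentile 0, and 12 rod genes used to gauge free RNA had medians of -0.98 and -0.85 in the same clusters. Cytokine genes had a median of -0.86 in cluster 13 (percentile 0.03) and 0.01 in cluster 14 (percentile 44.0), and complement genes -0.20 and -0.32 (percentiles 5.49 and 2.62). In thinned cells the complement median in cluster 13 turned to 0.104 and the cytokine median in cluster 14 to -0.30.

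In the microglia and macrophage class of the library labelled sponge, lists of opposite states were higher together. The homeostatic list was higher for 12 of 12 members (median 0.89, 0.83 to 1.0005, percentile 100) and the disease-associated list for 16 of 16 (median 1.04, 0.98 to 1.09, percentile 100). Tmem119, a marker of resting microglia, stood at 24.9 and 72.2 CPM, and Trem2, a lipid receptor of the disease-associated state, at 141 and 479 CPM. Antigen presentation genes had a median of 1.31 (15 of 15) and interferon response genes 0.71 (17 of 20), both at percentile 100. Lysosome and autophagy genes had a median of 0.60 (24 of 26, percentile 100), cytokine genes 0.49 (12 of 17, percentile 99.8) and complement genes 0.60 (11 of 16, percentile 100). With cells weighted equally the complement median was -0.0017. C1qa, C1qb and C1qc, the subunits that start the classical pathway, define the cluster, as do Cd74 and H2-Aa. At resolution 2, 1022 of its 1195 cells labelled GFP and 345 of its 724 labelled sponge lay in cluster 25, led by Igkc and macrophage genes, and 170 and 376 in cluster 26, led by Ctss and C1qa, so the mix of cells in the class differed between libraries.

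Endothelial cells of the library labelled sponge had higher antigen presentation genes (median 1.30, 15 of 15, percentile 100) and interferon response genes (median 0.65, 19 of 20, percentile 100). Their immediate early and heat shock list, which tracks stress during dissociation, had a median of 0.99 (19 of 22, percentile 100). Klf2, a transcription factor induced by blood flow, stood at 353 CPM (334 to 373) and 1338 CPM (1299.7 to 1376), Sox18 at 24.9 and 100.4 CPM, and Zfp36, an immediate early gene, at 185 and 575 CPM. Ptgs2, the inducible cyclooxygenase, stood at 39.1 CPM (32.9 to 46.3) and 7.35 CPM (4.80 to 10.8).

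Rods of the library labelled sponge had lower levels of oxidative phosphorylation genes. The 13 mitochondrially encoded genes were each lower in the library labelled sponge, with a median of -0.79 (-0.81 to -0.78, percentile 0), and nuclear genes of oxidative phosphorylation were lower for 37 of 46 members, with a median of -0.64 (-0.70 to -0.61, percentile 0). Cox7c stood at 565 and 242 CPM and Atp5k at 352 CPM (339.8 to 364) and 135 CPM (129 to 141). The members above 0 include Uqcrc1 at 68.3 and 87.9 CPM and Sdhd. Mitochondrial UMIs were 14.2% of the rod total in the library labelled GFP and 8.67% in the library labelled sponge. Under the stricter filter, which kept 419 and 3649 rods, the medians were -0.39 and -0.32.

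Genes of mitochondrial biogenesis and mitophagy had a median of 0.34 in rods (16 of 23 above 0, percentile 98.3). Phototransduction genes were higher for 24 of 25 members, with a median of 0.37 at percentile 85.7 of lists of like abundance, and Prph2, which shapes the outer segment discs, stood at 1099 and 1749 CPM. Gngt1 was the exception at 3254 and 2223 CPM. Antigen presentation genes had a median of 0.95 (14 of 15, percentile 100) and interferon response genes 0.47 (15 of 20, percentile 99.96). Psmb9 ranked highest in rods at 7.37 CPM (5.73 to 9.35) and 26.8 CPM (24.3 to 29.6), followed by genes such as Fam53b, Dusp12, H2-K1 and Psmb8. Of the genes ranked lowest, Mctp1 stood at 208 and 32.8 CPM, B3galt1 at 294 and 97.2 CPM, and Gng13, a G protein gamma subunit of ON bipolar cells, at 573 and 206 CPM. In rods glycolysis had a median of -0.07 (percentile 5.03), apoptosis 0.12 (percentile 64.9) and visual cycle genes -0.25 (percentile 0.59), the last with RPE genes such as Ttr at 931 and 525 CPM. Lysosome and autophagy genes had a median of -0.06 (percentile 2.47), which turned to 0.08 under the stricter filter, and the glycolysis median to 0.006.

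In cones, phototransduction genes were higher in the library labelled sponge for 14 of 14 members (median 0.83, 0.76 to 0.88, percentile 100), although Arr3, Opn1sw and other members define the cluster. Antigen presentation had a median of 0.69 (12 of 12, percentile 99.98) and the interferon response 0.73 (7 of 9, percentile 99.8). Klk6 had 0 counts in the library labelled GFP and 34.02 CPM (25.9 to 43.9) in the library labelled sponge, a log2 ratio of at least 3.98. Apod, a lipocalin, stood at 13.6 and 122 CPM.

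In bipolar cells the immune lists came apart, and in amacrine cells this depended on the settings. Antigen presentation genes had medians of 0.84 in bipolar cells (14 of 15) and 1.26 in amacrine cells (15 of 15), both at percentile 100, whereas interferon response genes had medians of -0.11 (7 of 20, percentile 25.2) and -0.07 (8 of 20, percentile 11.0). The latter turned to 0.39 in amacrine cells thinned to 1000 UMIs, to 0.0845 with 5 added to the counts and to 0.0698 for genes with at least 100 counts. Cd74 and H2-Aa of the antigen presentation list also lead the microglia and macrophage cluster. Free RNA of immune cells was weighed for RPE alone. In the other classes, rods and cones among them, it was not told apart from expression. Oxidative stress genes had medians of -0.31 and -0.25 in bipolar and amacrine cells, at percentiles 0.02 and 0.04. Bipolar cells of the library labelled sponge had more Sebox at 84.2 and 224 CPM, a gene of rod bipolar cells. The largest cluster of rod bipolar character held 40.6% of bipolar cells in the library labelled GFP and 52.0% in the library labelled sponge. The smaller clusters of that character went the other way, cluster 24 with 0.865% and 0.181% of kept cells and cluster 25 with 0.387% and 0.159%. Amacrine cells had Esr1, the oestrogen receptor, at 32.1 and 94.3 CPM and the activity-dependent factor Npas4 at 12.4 and 36.6 CPM.

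Beyond rods, mitochondrially encoded genes had medians from -1.38 in Müller cluster 13 to -0.25 in RPE, and nuclear oxidative phosphorylation genes from -0.69 in Müller cluster 13 to 0.02 in RPE. In RPE these lay at percentiles 9.21 and 62.5 of lists matched on CPM, but with lists matched also on transcript length the nuclear genes lay at percentile 1.42 in RPE and 6.11 in cones. Free rod RNA moved alongside: the 12 rod genes had medians from -0.98 in Müller cluster 13 to -0.30 in cones in every class outside rods, and the medians in RPE and in the microglia and macrophage class turned to 0.50 and 0.24 in thinned cells.

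**Figure D4:**
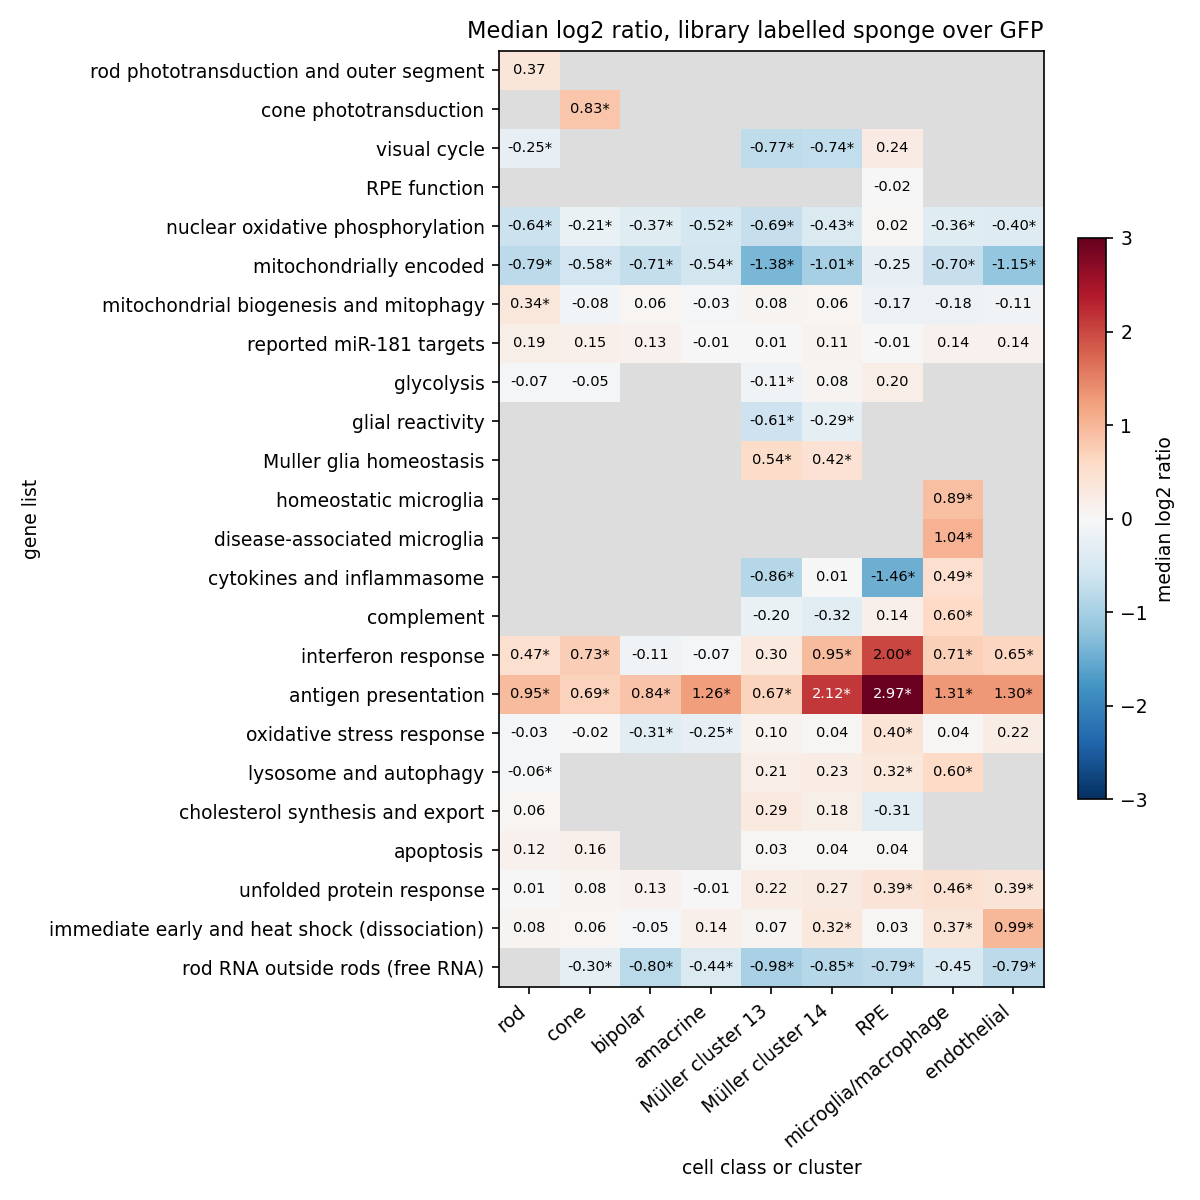
Median log2 ratio (library labelled sponge over library labelled GFP) of each gene list in each class; an asterisk marks a median outside the central 95% of random lists matched on CPM, and grey marks combinations that were not compared. Antigen presentation is above 0 in every class, from 0.67 in Müller cluster 13 to 2.97 in RPE.

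The direct readout of the sponge is the set of genes with a miR-181a/b seed match in the 3' UTR, which repression by the microRNA would hold down. The shift was taken over all cells of a class. In the library labelled sponge eGFP was seen in 28.6% of RPE cells, and elsewhere in 1.02% of endothelial cells to 4.67% of cones. If eGFP marks the vector, a shift outside RPE rests mostly on cells in which it was not seen. In rods the median of 2606 genes with a match differed from that of 11187 genes with none by 0.0027 (-0.0083 to 0.02), at percentile 33.0 of lists matched on CPM and UTR length. Shifts lay between -0.09 and 0.0027 outside RPE. In RPE the shift was -0.20 (-0.21 to -0.18) at percentile 0.12, but the 210 7-mers of the same base composition had a median shift of -0.19 there and the seed ranked 138. Bipolar cells lay at percentile 2.38, Müller cluster 14 at 2.52 and endothelial cells at 3.31. Counted from the highest shift, the seed ranked 93 in bipolar cells, 5 in cones, 13 in microglia and macrophages, and from 33 to 55 in the others. With lists matched on UTR length and AT content in place of CPM, the RPE percentile was 41.1. Those of cones and of the microglia and macrophage class were 99.2 and 99.7, against 68.8 and 41.6 with lists matched on CPM and UTR length. This background dropped the match on CPM, so these moves cannot be credited to AT content alone. In the other classes the percentiles with AT content ranged from 65.7 in endothelial cells to 95.7 in rods.

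Genes reported as miR-181 targets had medians between -0.01 and 0.19, at percentiles from 12.8 to 90.5, and that of the microglia and macrophage class turned from 0.14 to -0.12 in thinned cells. In rods the median was 0.19 (15 of 20 above 0, percentile 65.9), with the mitochondrial regulator Nrf1 at 77.2 and 111 CPM, the survival gene Bcl2 at 53.8 and 87.0 CPM and the neural factor Prox1 at 132 and 75.2 CPM. In RPE the median was -0.01 (8 of 19, percentile 65.5), or 0.23 with median-of-ratios scaling.

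**Figure D5:**
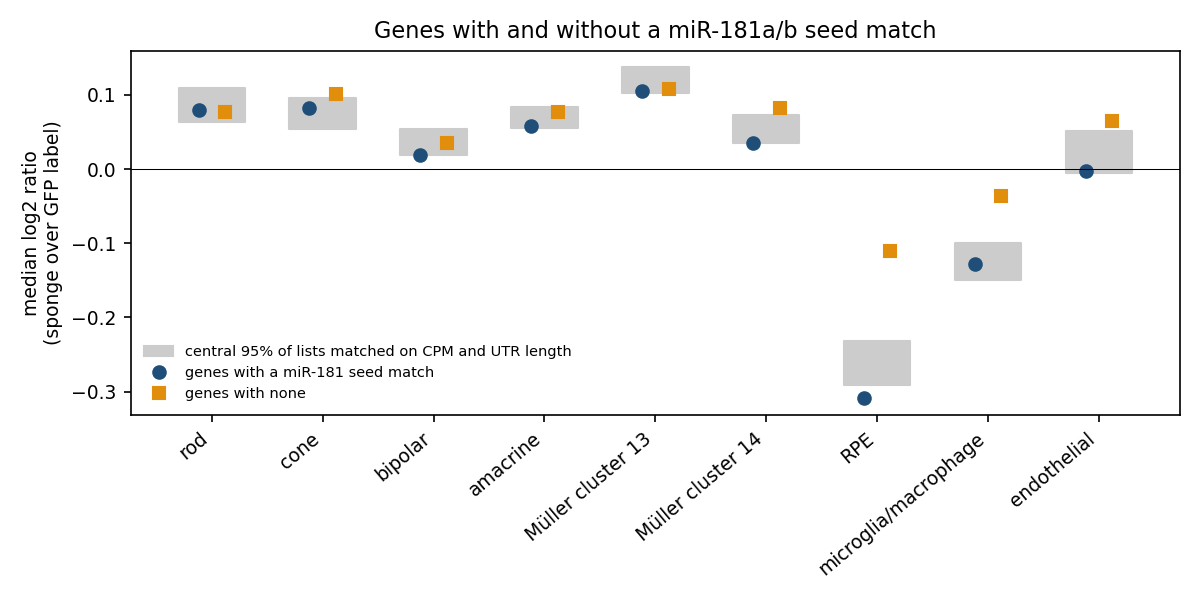
Median log2 ratio (library labelled sponge over library labelled GFP) of genes with and without a miR-181a/b seed match in each class; grey bands hold the central 95% of lists matched on CPM and UTR length. In rods the medians differ by 0.0027, and in RPE by -0.20.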

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

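The test of free RNA as a source of eGFP was chosen only after the result was seen.

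The eGFP feature, which enters no comparison of gene lists, had 5484 UMIs in the library labelled sponge and 12 in the library labelled GFP, a signal outside the main measurement and above the control library. Free RNA or misread bases would spread it over all classes, and its CPM in RPE was 72.9 times that in rods of the same library, which argues against that source. A swap of the labels stays open. If the library labelled sponge were the GFP control, seed-matched genes would be lower in its RPE. They were at percentile 0.12 there, but the seed ranked 138 of 210 7-mers of its composition, so the shift is not specific to miR-181. With lists matched on UTR length and AT content in place of CPM, RPE lay at percentile 41.1. Cones and microglia lay at 99.2 and 99.7 under that background, the direction that the labels predict, and the seed ranked 5 and 13 there. With lists matched on CPM and UTR length those 2 classes lay at 68.8 and 41.6, with shifts of -0.02 and -0.09. Expression of a sponge vector that encodes eGFP also stays open, since seed-matched genes in RPE cells with eGFP lay at percentile 88.3 against cells without, and a control vector whose GFP differs from the eGFP feature was not tested. The direction of each comparison therefore cannot be told apart from its mirror by these data.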

How the results depend on the processing

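Alternatives that left out cells with high Scrublet scores, left out unnamed clusters, counted cluster 7 with rods, weighted cells equally for the lists or took an RPE cluster of resolution 2 alone were chosen after seeing the data. Of 1046 values of named genes under the alternatives, 1046 kept their sign, as genes picked for their distance from 0 would, and 264 lay outside their main interval. Of 1326 values of lists 1243 kept their sign. Reversed is used here as a label that only some changes of sign carried, 7 of them among lists. A further 267 list values lay outside the main interval without that label, and some of these changed sign. In RPE, for example, the RPE function list went from -0.02 to 0.22 with median-of-ratios scaling. The complement list there went from 0.14 to -0.33 in cluster 34 alone. Of 64 values of shares 54 kept their sign, and of 45 values of the seed match 37. Keeping the doublet calls was not run, since none were made, and 22 named-gene values with 3 or fewer counts left after subtraction of the rod profile were left out. No cluster was named amacrine at resolution 2. There cluster 6 scored highest for amacrine cells but stayed unnamed as mixed with fibroblasts, and cluster 33 was named as resembling horizontal cells, a class not named at resolution 1. With 1 library per group, none of this covers differences between animals, and the depth per class limits genes under 20 counts.

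The stricter filter gave log2 ratios of the shares of 3.30 for rods, 1.35 for cones, 0.44 for bipolar cells (reversed), -1.28 for amacrine cells, -0.92 for RPE and -0.58 for microglia and macrophages. Assignment by marker score gave -0.0407 for bipolar cells, -0.52 for cones, -0.26 for amacrine cells, -0.44 for RPE and 0.42 for microglia and macrophages, and turned ocular surface epithelium to 0.82 and pericytes to 0.0318. Among neural retina cells the values were 0.72 for rods, -0.46 for bipolar and -1.24 for amacrine cells. Without high Scrublet scores they were 0.67 for rods, -0.41 for bipolar cells and 0.34 for microglia and macrophages. Without unnamed clusters they were 0.98 for rods and -0.21 for bipolar cells, and cluster 7 counted with rods gave 1.14.

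In RPE the antigen presentation median was 3.21 with median-of-ratios scaling, 2.74 in thinned cells, 0.57 in cluster 34 alone and 1.83 in cluster 43 alone, and the interferon median 2.24 with median-of-ratios scaling and -0.38 in cluster 34 alone (reversed), a cluster set apart from the other partly by interferon genes. The interferon median in Müller cluster 14 was 0.64 in thinned cells and 0.76 under the stricter filter. The mitochondrially encoded median in rods was -0.83 with median-of-ratios scaling, -0.91 with totals that leave these genes out, -0.74 in thinned cells, -0.39 under the stricter filter, -0.84 without high Scrublet scores and -0.73 with cells weighted equally, and the nuclear oxidative phosphorylation median -0.76 with those totals and -0.32 under the stricter filter. Among the other lists, the values labelled reversed included cytokines in RPE at 0.43 in thinned cells and 2.02 in cluster 43 alone. Free rod RNA in RPE was labelled so at 0.50 in thinned cells and 0.55 with cells weighted equally. The rest were complement in microglia and macrophages at -0.0017 with cells weighted equally, and lysosome and autophagy in rods at 0.0805 under the stricter filter. Changes of sign without the label are not listed here.

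With 8mer sites only the seed shift was -0.25 in RPE, -0.11 in microglia and macrophages, -0.10 in endothelial cells, 0.0181 in Müller cluster 13, 0.0029 in bipolar cells (reversed), 0.0045 in cones and 0.026 in rods. With at least 2 sites it was -0.27 in RPE, -0.17 in microglia and macrophages, -0.10 in endothelial cells, 0.0175 in Müller cluster 13, -0.0499 in cones and 0.0019 in bipolar cells (reversed). With at least 100 counts it was -0.22 in RPE, -0.0271 in bipolar cells and 0.0015 in cones. Matching on UTR length and AT content, without CPM, gave percentiles of 41.1 in RPE, 86.4 in bipolar cells, 99.2 in cones and 99.7 in microglia and macrophages. The cause of these differences was not tested.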

Other observations

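The test of a response in cells that express the vector and that of damaged cells were chosen after the result was seen, as were the comparison of cells with no eGFP and the alternatives by RPE cluster.

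Within the RPE of the library labelled sponge, cells with eGFP differed from cells without it. With every cell thinned to 1000 UMIs, 73 cells had eGFP and 425 had none, and Iigp1 stood at 1126 CPM (896 to 1398) in the cells with eGFP and 275 CPM (228 to 330) in those without. Gbp4 stood at 302 CPM (189 to 457) and 115 CPM (85.3 to 152), and Cd74 at 1167 CPM (932 to 1443) and 633 CPM (559.6 to 713). Rpe65 stood at 3694 and 3675 CPM. Antigen presentation genes had a median of 1.12 (11 of 12, percentile 100), interferon response genes 0.43 (7 of 9, percentile 97.7) and glycolysis genes -0.34 (6 of 18, percentile 0.04). Cells with eGFP had a median of 18043 UMIs before thinning and those without 2736.

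Antibody transcripts set the microglia and macrophage class of the libraries apart. Igha stood at 1.67 CPM (0.673 to 3.45) in the library labelled GFP and 2043 CPM (2000.4 to 2087) in the library labelled sponge, and Igkc at 155 and 14259.8 CPM. Both lead the cluster, so they are part of what defined it. Ighg2c had 0 counts in the library labelled GFP and 487 CPM in the library labelled sponge, a log2 ratio of at least 9.41. These are products of plasma cells, for which no marker list other than that of B cells was fixed.

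The interferon and antigen presentation genes that were higher in RPE of the library labelled sponge were weighed against 3 explanations. RNA of immune cells would have to make up 64.4% of the RPE RNA to give the gain, against the 0.779% that abundant immune genes show (0.376 to 8.48 over 10 genes), a ratio of 82.7 for microglia and a larger one for T and NK cells, which argues against it. A difference in UMIs per cell as the whole cause is argued against by the pooled median at 1000 UMIs per cell, which was 1.003 times the main one. Members were filtered anew on the thinned counts, so these 2 medians cover unlike sets of genes. The antigen presentation median alone was 2.74 in thinned cells, outside its main interval. A response in cells that express the vector is a candidate explanation: the pooled median between RPE cells with and without eGFP was 0.89 at percentile 100, with 18 of 21 members higher, but the 355 cells with no eGFP UMI at full depth, in which low expression of the vector can be missed, also stood above RPE of the library labelled GFP when both were thinned (pooled median 2.12, 19 of 21 members higher, Cd74 at 507 and 64.1 CPM). Cells with eGFP also had less free rod RNA (median -0.61, percentile 0), a mitochondrially encoded median at percentile 2.35, a dissociation list at percentile 97.1 and a larger share in cluster 43 (65.8% against 50.8%), so cell quality moved with this contrast, and whether the vector, its dose, the injection or the sponge is behind it was not tested.

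Nuclear oxidative phosphorylation genes that were lower in rods of the library labelled sponge have short transcripts. Matching random lists on transcript length as well as CPM left the list at percentile 0, with a matched median of -0.26 against -0.64, which argues against length as the whole cause but may leave it a part. Cells damaged in dissociation stay open: under the stricter filter the median was 0.496 of the main one, at percentile 0, but this filter selects on mitochondrial UMIs and kept 419 of 5465 rods labelled GFP and 3649 of 5879 labelled sponge, so damage cannot be told apart from a difference in mitochondrial transcripts. An effect of the sponge on mitochondria is what the design would name, and it was not tested apart from these.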
